A study of Mus musculus with 12 samples.

How the data were processed

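Total RNA from sorted bone marrow cells of mice was amplified, labelled with Cy3 together with spike-in controls and hybridised to one-colour Agilent arrays of 62976 spots. The 12 arrays hold 1 array for each of 6 conditions in each of 2 cell types. The cell types were LSK cells, the lineage-negative, Sca-1-positive, c-Kit-positive fraction that contains stem and multipotent progenitor cells, and granulocyte-macrophage progenitors (GMPs). The conditions were wild-type, Tet2 knockdown, Ezh2-null, double mutant, double mutant with a myelodysplastic/myeloproliferative disease (MDS/MPN) and double mutant with refractory anaemia with excess blasts (RAEB). No group was repeated, and the labels do not say how many mice gave each RNA or whether both cell types of a condition came from the same mice. For MDS/MPN and for RAEB the sex-linked signals were opposite in the 2 cell types, which argues against a shared donor there.

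Per the file headers, the deposited scanner files were made with Feature Extraction 10.7.1.1, and their processed signal is a background-corrected intensity on a linear scale. The deposited median signals of spot and background are intensities as well. The deposited columns for saturation, outlying spots, control type and signal well above background are flags, a unit recorded as other. The authors' value table holds the processed signal itself: its intensity equalled that of the scanner files at all 62976 spots of each array, so it gave the same results as the scanner files. No array had a saturated gene spot among its 59305 gene spots. The 75th percentile of the processed signal ran from 168.5 to 389.4 between arrays, and 45.6 to 52.3% of gene spots lay well above background. The median coefficient of variation of replicate probes ran from 4.36 to 5.27%. The number of arrays limits the precision of every value.

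Each array was scaled by subtracting the log2 of its 75th percentile from the log2 processed signal, so a value of 0 means the array's own 75th percentile. Spots of 1 probe were averaged. The files do not pair probes with gene symbols; probes were named through the unversioned RefSeq accession that they carry and a gene table of the GRCm38.p6 assembly, used for names only since the headers name another build. Of 55681 distinct gene probes, 26762 matched 1 symbol, 0 matched several and 28919 had none; the matched probes gave 20284 symbols, and 97.92% of the NM and NR accessions matched. For each gene the probe with the highest mean over the 12 arrays was used, and a gene was tested where that probe was well above background on at least 2 of the 12 arrays. This left 13706 genes.

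Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Because no group was repeated, replication came from the design. GMP and LSK were compared over all 12 arrays with condition as a block. Ezh2 loss and Tet2 knockdown were each tested as 4 against 4 of the 8 arrays without disease, with cell type and the other genotype as terms, so the test is of an effect shared by both cell types. The LSK and GMP arrays of a genotype counted as separate arrays, with no term for a donor that they may share. The SE and adjusted p therefore do not measure the spread between mice. The same 8 arrays gave the Tet2 by Ezh2 interaction and the difference between the Ezh2 effects in GMP and LSK. The double mutant against wild-type, the diseased against the other double mutants, and RAEB against MDS/MPN were contrasts in a fit of all 12 arrays with cell type and condition. Where a setting left 1 array alone in a group, limma pooled the spread, and the lone array was assumed to vary like the others. Differences between single arrays were not tested: genes were counted where they differed by at least 2-fold, a log2 difference of 1, with the brighter array well above background.

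The 33 gene lists held 756 listed names, 752 of which have a current symbol. Of the lists, 30 were tested with limma's camera at a preset correlation of 0.01, adjusted over lists within a comparison; the sex-linked list was left out and lists with under 3 genes tested were not run. An estimated correlation was the alternative, and with it 0 lists passed in any comparison. For single arrays a list's median difference was placed among those of 10000 random lists matched on mean expression, which treats genes as independent.

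The genes named in the text were chosen by a rule: Tet2 and Ezh2 in every comparison; up to 8 genes with the largest differences in each direction among those past the threshold; where fewer than 8 passed, up to 5 of the largest differences that had the same sign in every matched pair of arrays, given as values; up to 4 members with the smallest p for each list described; and up to 5 in each direction for single arrays. A named gene had to carry an ordinary symbol and be well above background on every array of the brighter group. Where the dimmer group lay at background on each of its arrays, the fold is given as "at least", computed against the dimmer array's signal or the lowest signal called well above background on that array, whichever was larger. It is a bound under the main scaling and background correction only, and the alternatives could give smaller sizes. The groups, tests, lists, naming rule and a first set of alternatives were fixed before the data were examined.

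The fits were tested on simulated data made for each comparison, with 50 changed genes of each size among 13706. For Ezh2 loss, 18% of genes changed 1.5-fold, 60% of those changed 2-fold and 82% of those changed 4-fold were recovered. For Tet2 knockdown the shares were 28%, 58% and 78%. Unchanged genes were called as well: 15 for Ezh2 loss, 11 for Tet2 knockdown and 1 to 7 for the other comparisons. The shares hold for this number of changed genes, since the adjustment depends on how many genes change. For the interaction and for the difference of Ezh2 effects between cell types, 0% were recovered at 2-fold, and 30% and 40% at 4-fold. At 4-fold, 92% were recovered for GMP against LSK, 54% for the double mutant against wild-type, 70% for the diseased arrays and 48% for RAEB against MDS/MPN. In 100 simulated data sets for Ezh2 loss, a shifted list of 20 genes was called 100 times and an unshifted list 1 time. The simulated genes varied independently of each other, so this does not check the list test where genes of a list move together.

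The alternatives were quantile normalization; normexp background correction with an offset of 50; the authors' value table; no filter; a filter of at least 6 of 12 arrays; the mean over probes of a gene; eBayes with trend and robust options; slide as a block; no condition block; the fit of 12 arrays for the genotype effects; only the arrays compared; and leaving out each array in turn. The files hold no mean signal, so normexp was run on the median signals of spot and background. The authors' value table equals the main values, so it is no independent check, although counts of alternatives include it. After the data had been seen, 5 more were added: the arrays' sex pattern as a covariate, probes without a symbol kept, slide as a random block for disease, GMP against LSK on the 8 arrays without disease, and leaving out probes in the outermost 20 lines and 10 columns of spots. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6 for the tables. The values of 3 genes are not reported here, although these genes stayed in every fit, list and count.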

Results

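Gene expression was measured on 12 arrays of sorted mouse bone marrow cells, 6 of LSK cells and 6 of granulocyte-macrophage progenitors (GMPs). The cells grew in recipient mice from transplanted fetal liver cells of 4 genotypes: wild-type, Tet2 knockdown, Ezh2-null and both together (double mutant). Tet2 oxidises methylated cytosine in DNA, and Ezh2 is the catalytic subunit of the Polycomb complex PRC2, which methylates histone H3. In each cell type 1 further array came from double mutant cells of mice with MDS/MPN and 1 from those of mice with RAEB. There was 1 array for each cell type and condition, so no value of a single group has a replicate error. Values are log2 signals relative to the array's own 75th percentile, and differences are log2 differences with their standard error (SE) from limma. This SE reflects how far effects differed between cell types and conditions, and not the spread between mice. The 8 arrays without disease shared 1 slide; the 2 diseased LSK arrays shared another slide, as did the 2 diseased GMP arrays.

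Tet2 signal was lower with the knockdown in each of the 4 matched pairs of arrays. In LSK cells it was 0.44 in wild-type and -1.61 with the knockdown, and 0.12 in Ezh2-null against -0.79 in double mutant cells. In GMPs it was 1.57 in wild-type and -0.64 with the knockdown, and 1.51 in Ezh2-null against -1.01 in double mutant cells. The difference was -1.92 (SE 0.27, 4 arrays against 4) and did not pass the threshold (adjusted p = 0.379, range over the alternatives 0.0979 to 1.00). On the diseased arrays Tet2 was -1.27 (LSK MDS/MPN), -1.22 (LSK RAEB), -1.77 (GMP MDS/MPN) and -3.09 (GMP RAEB). The Ezh2 probe read between 2.50 and 3.41 on the 12 arrays and differed by 0.01 (SE 0.12, adjusted p = 0.995) between Ezh2-null and Ezh2 wild-type arrays; where the probe lies relative to the deleted part of the gene is not known, so it does not check the genotype.

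The sex-linked genes separated the arrays in a way that crosses the genotypes. Xist, the RNA of the inactive X chromosome, read 2.57 (LSK) and 1.63 (GMP) on wild-type arrays and 2.52 and 1.17 on double mutant arrays, where the Y-linked Eif2s3y, Ddx3y and Uty lay at background. Tet2 knockdown and Ezh2-null arrays had the opposite pattern, with Eif2s3y between 1.48 and 2.68 and Xist between -6.15 and -4.36. Among the diseased arrays, both LSK arrays had high Xist (1.35 and 1.63) and both GMP arrays high Eif2s3y (1.51 and 0.82). Within MDS/MPN and within RAEB this argues against the same donor for both cell types, although the condition block matches them. The pattern is balanced over Ezh2 loss and over Tet2 knockdown, and coincides with their interaction.

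**Figure D1:**
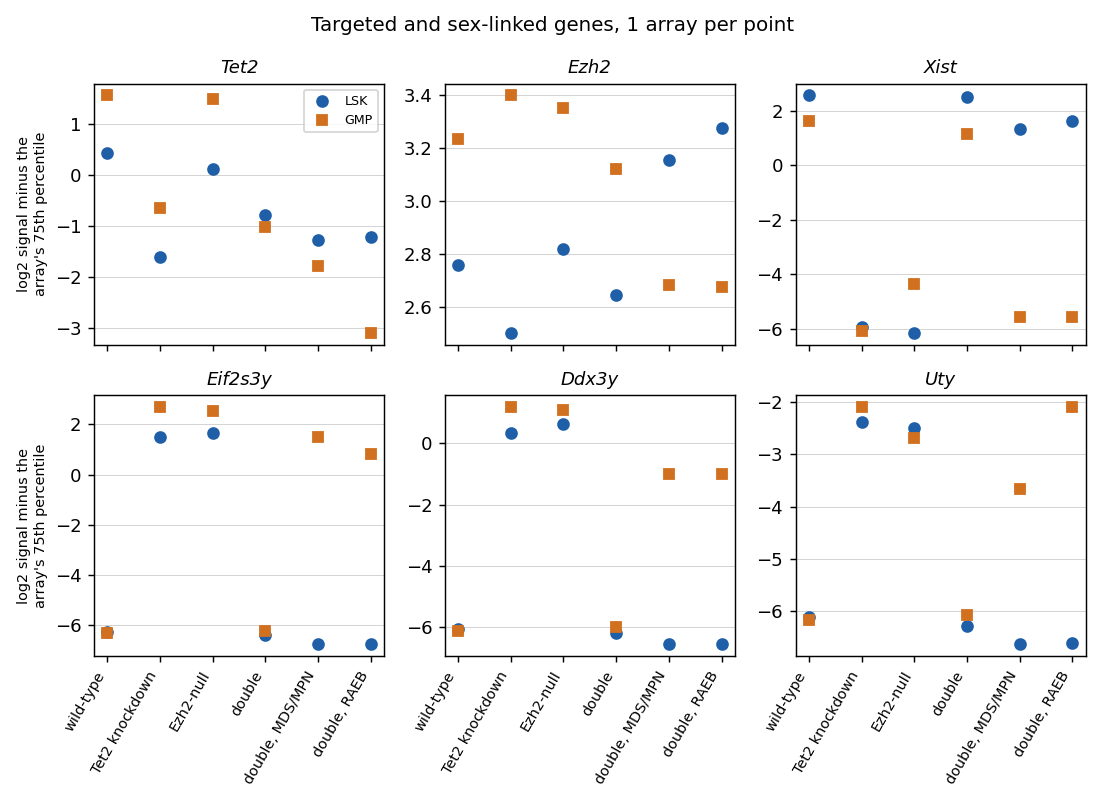
Log2 signal minus the array's 75th percentile (y axis) of Tet2, Ezh2, Xist, Eif2s3y, Ddx3y and Uty for the 6 conditions (x axis), with 1 point per array, circles for LSK and squares for GMP. Tet2 lies lower on each knockdown array than on its match, and Xist and the Y-linked genes split the arrays into opposite sets, with Xist at 2.57 and Eif2s3y at -6.25 in wild-type LSK cells.

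GMPs and LSK cells were compared to describe the 2 populations themselves. GMPs had far higher expression of granule and myeloid genes: the neutrophil elastase gene Elane rose by 5.94 (SE 0.39), the GMP gene Ms4a3 by 5.99 (SE 0.48), Mefv, the gene for pyrin, by 6.21 (SE 0.46) and the glutathione peroxidase gene Gpx3 by 6.01 (SE 0.45). Chst13 (6.39), Nrg1 (6.36), Celsr3 (5.95) and Igsf6 (5.93) rose as much. LSK cells had far more of the DNA polymerase gene Dntt, used in lymphoid antigen receptor rearrangement, which was -9.99 (SE 0.19) in GMPs. Mycn was at least 209-fold lower in GMPs, Gimap8 at least 127-fold and Mn1 at least 111-fold. Here "at least" marks a group whose arrays all lay at background for the gene, under the main scaling. Over the alternatives the log2 differences ran from -8.10 to -4.06 for Mycn, -7.43 to -2.85 for Gimap8 and -6.98 to -2.88 for Mn1. The endothelial and stem cell genes Robo4 (-8.29) and Esam (-7.59), and Slc16a11 (-7.27) and Wfdc18 (-6.88), were also lower. Sizes against arrays partly at background are not exact: Robo4 (-8.96 to -4.62 over the alternatives), Esam (-8.42 to -3.99), Wfdc18 (-8.09 to -3.69) and Gpx3 (2.84 to 6.50) were well above background on 1 of the 6 dimmer arrays, and Chst13 (3.78 to 6.94), Nrg1 (3.60 to 7.09) and Celsr3 (2.99 to 6.68) on 2. Each of these 16 genes had the same direction in 6 of 6 conditions, with adjusted p of at most 0.000226.

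Among the gene lists, haematopoietic stem cell genes fell in GMPs (33 of 35 tested, median -2.73), with Mycn at least 209-fold and Gata3 at least 36.6-fold lower, Gfi1b at -4.29 and Meis1 at -3.33. Lymphoid-primed progenitor genes fell (15 of 18, median -2.42), including Dntt and Il7r (at least 21.3-fold). Interferon response genes fell (31 of 37, median -1.04), with Ifit3 at least 25.6-fold lower, Ifi44 at -4.73 and Rsad2 at -3.46. Genes of the granulocyte-macrophage progenitor list rose (21 of 24, median 2.65), such as the protease gene Prtn3 (4.05) and Fcgr2b (3.28). Mast cell, basophil and eosinophil genes rose too (16 of 21, median 2.70), with the histamine enzyme gene Hdc at 5.72 and the eosinophil granule genes Prg3 at 5.32 and Epx at 4.86, as did monocyte and macrophage genes (11 of 20, median 2.10), with Cd14 at 5.34 and Csf1r at 2.41. With an estimated correlation the adjusted p of these lists was 0.108, 0.174, 0.0634, 0.174, 0.220 and 0.262, in the order given. Adjusted over the list alone, the counts were 33, 15, 32, 21, 16 and 11.

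Lists of other lineages were lower in GMPs. Erythroid genes fell (15 of 23, Hbb-b2 at -5.95 and Car2 at -5.04), as did megakaryocyte and platelet genes (14 of 23, Gp9 at -2.67), T and NK cell genes (13 of 19, Lck at -4.15), B-lymphoid genes (5 of 12, Blnk at -3.86) and dendritic cell genes (8 of 13, the MHC class II genes H2-Eb1 at -6.06 and H2-Aa at -5.13). With an estimated correlation their adjusted p was 0.0543, 0.364, 0.262, 0.465 and 0.108. Adjusted over the list alone the counts were 15, 14, 14, 5 and 8. HoxA genes fell (6 of 9, Hoxa3 at -2.40 and Hoxa9 at -1.78, adjusted p = 0.364 with an estimated correlation) and HoxB genes fell (3 of 5, Hoxb5 at least 10.4-fold, adjusted p = 0.465 with an estimated correlation), with 7 and 3 adjusted over the list alone. Haematopoietic oncogenes (15 of 25, Pim2 at -2.87), TGF-beta and BMP signalling genes (14 of 21, Tgfbr3 at -3.20) and Wnt signalling genes (6 of 22, Fzd6 at -1.83) were lower. Their adjusted p with an estimated correlation was 0.0543, 0.174 and 0.537, and their counts adjusted over the list alone were 15, 14 and 3. Haem synthesis and iron genes (12 of 19, Alas1 at 3.60) and proliferation genes (10 of 37, Ccne1 at 1.49) were higher, with adjusted p of 0.363 and 0.796 with an estimated correlation and counts of 12 and 6 adjusted over the list alone. With quantile normalization the HoxB (adjusted p = 0.0784), B-lymphoid (0.144), Wnt (0.122) and proliferation lists (0.7497) no longer passed. Neutrophil genes had no call (8 of 22 higher, 2 lower, also when adjusted over the list alone, camera adjusted p = 0.143).

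In all, 6108 of 13706 genes passed the threshold, 3525 higher and 2583 lower in GMPs (57.7% higher). Quantile normalization turned this split to 2641 higher and 3105 lower. The median difference of all genes was 0.16 with the 75th percentile and 0.01 with quantiles, and the cause of the turn was not tested. Tet2 (0.15, adjusted p = 0.792) and Ezh2 (0.22, adjusted p = 0.450) did not differ beyond the spread in the main limma fit. Over the alternatives Ezh2 ran from -0.01 to 0.60 and passed in 2 of 24, and Tet2 passed in 0 of 24.

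Ezh2 loss raised a small set of genes in both cell types. Bmpr1a, which encodes a receptor for bone morphogenetic proteins, rose at least 21.9-fold (4.47, SE 0.33, 3.82 in LSK cells and 5.12 in GMPs). Dsp, the desmosomal protein desmoplakin, rose by 3.62 (SE 0.36), the neuronal kinase-like gene Camkv by 3.01 (SE 0.35), the phosphatase gene Ppm1e by 2.77 (SE 0.15), Ly6k by 2.71 (SE 0.30), and Ninl at least 8.58-fold. Pbx3, a homeodomain partner of Hox proteins, rose by 1.91 (SE 0.18) and the centromere protein gene Cenpv by 1.83 (SE 0.12). Hoxb2 fell by 1.95 (SE 0.21), the scavenger receptor gene Scarf2 was 2.82-fold lower and the complement protease gene C1rb fell by 1.20 (SE 0.14). Each had the same sign in 4 of 4 matched pairs, with adjusted p from 0.00743 to 0.0456. Dsp, Camkv, Ppm1e and Ly6k lay well above background on 2 of the 4 Ezh2 wild-type arrays, so their sizes are not exact. Their lowest values over the alternatives were 1.28, 1.14, 1.18 and 1.26. Bmpr1a and Ninl, at background on all Ezh2 wild-type arrays, came down to 1.12 and 0.81. The call held in 16 of 19 alternatives for Ppm1e, 14 for Bmpr1a and Cenpv, and 9 for Pbx3 and Scarf2. It held in 7 for Dsp and Camkv, 6 for Ninl and Ly6k, 5 for Hoxb2 and 4 for C1rb. Each of these counts includes the authors' value table, which equals the main values and keeps every call by construction.

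In total 23 genes rose and 3 fell with Ezh2 loss. Among the other 15 that rose, chosen for naming after their values were seen, were Tulp4 (at least 6.05-fold), Fam169a (at least 5.74-fold), the hypoxia factor gene Hif3a (1.05) and Bmi1 (1.40), a core gene of the Polycomb complex PRC1 and the 1 member of the 18 tested PRC1 genes that passed. Of the 10 other PRC2 genes tested, 0 passed, also when adjusted over the list alone; limma gave 1205 genes at an unadjusted p under 0.05 for Ezh2 loss, against 685.3 by chance. Among the lower genes that did not pass were C1qtnf6 (-2.47, adjusted p = 0.0617) and Gstm2 (-2.38, adjusted p = 0.155). Tet2 differed by 0.01 (adjusted p = 0.997).

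**Figure D2:**
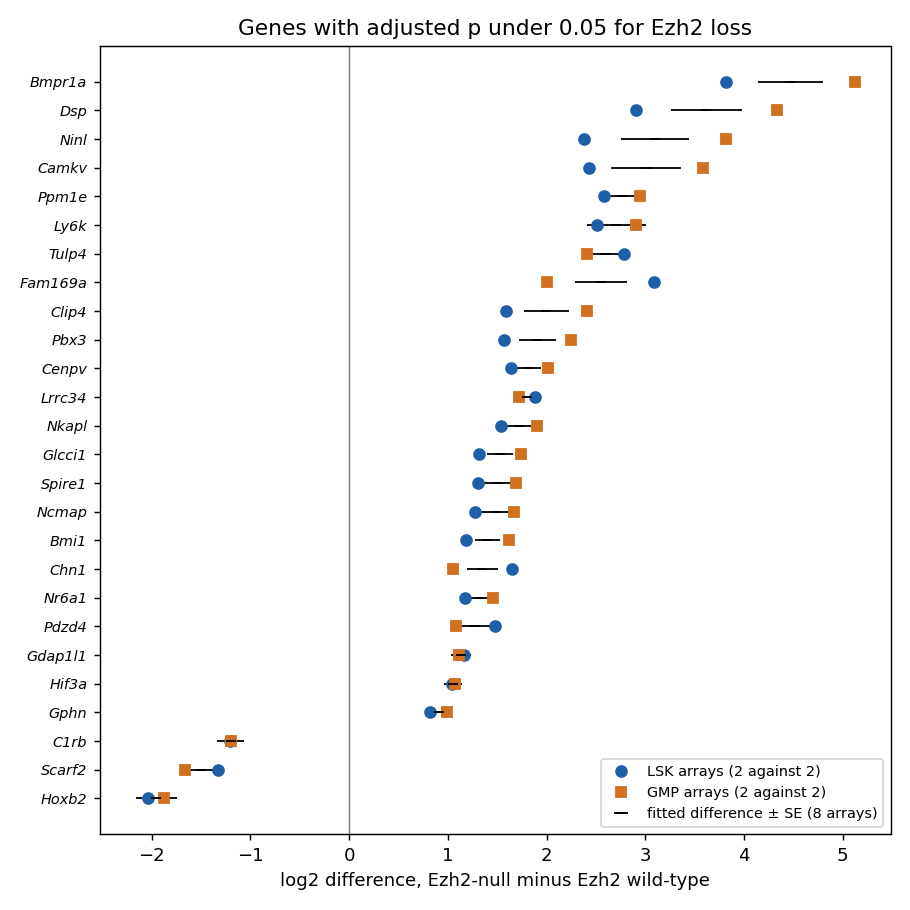
Log2 difference between Ezh2-null and Ezh2 wild-type arrays (x axis) for the 26 genes with an adjusted p under 0.05 (y axis), with bars for the fitted difference and its SE over 8 arrays, circles for the LSK arrays and squares for the GMP arrays (2 against 2 in each). The genes lie on the same side of 0 in both cell types, from Bmpr1a, at background on the Ezh2 wild-type arrays and fitted at 4.47, to Hoxb2 at -1.95.

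The gene lists moved by less with Ezh2 loss. Interferon response genes rose as a list (30 of 37 positive, median 0.28), with values of 1.23 for Ifit3, 1.13 for Ifi44 and 1.01 for Usp18; no member passed over all genes, and 11 passed adjusted over the list alone. Lymphoid-primed progenitor genes rose (14 of 18 positive, median 0.40), with Ccr9 at 2.01 and Dntt at 0.95, neither past the threshold; 4 passed adjusted over the list alone, and the effect was smaller in GMPs than in LSK cells (median of the differences -0.52, 2 of 18 positive, adjusted p = 0.305 with an estimated correlation). HoxB genes fell (0 of 5 positive, median -0.67, Hoxb2 the 1 call, also adjusted over the list alone) and HoxA genes rose (7 of 9 positive, median 0.51, Hoxa10 at 1.78, not past the threshold, 1 passed adjusted over the list alone). Neutrophil genes fell (3 of 22 positive, median -0.39, Camp at -1.72, not past the threshold, 0 adjusted over the list alone). Under an estimated correlation the adjusted p of each of these 5 lists was 0.649. Within LSK cells and within GMPs the medians were -1.48 and 0.13 for HoxB and -0.01 and 0.41 for HoxA genes, so neither direction was seen in both. The wild-type LSK array had higher neutrophil genes than the other LSK arrays without disease: their list medians against it were -1.72 with Tet2 knockdown, -1.51 in Ezh2-null and -1.26 in double mutant cells.

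Genes of the fetal and imprinted growth list also rose as a list with Ezh2 loss (9 of 13 positive). Its members with the largest values were Igf2bp3 (at least 13.1-fold), Lin28b (at least 7.69-fold) and Hmga2 (2.40, SE 0.39), genes best known from fetal cells, and none passed over all genes (adjusted p = 0.226, 0.170 and 0.114); 3 members passed adjusted over the list alone. Cyclin-dependent kinase inhibitor genes (6 of 7 positive, median 0.41, Cdkn2c at 0.43), TGF-beta and BMP signalling genes (13 of 21, Thbs1 at least 2.39-fold), p53 target genes (17 of 22, Fas at 1.00), Wnt signalling genes (14 of 22, Fzd2 at 1.36) and proliferation genes (29 of 37, Ccna2 at 0.22) were higher as lists. Haematopoietic stem cell genes were lower as a list (8 of 35 positive, Esam at -0.63), with medians of -0.30 in LSK cells and 0.09 in GMPs. The adjusted p with an estimated correlation was 0.649 for the fetal, kinase inhibitor, TGF-beta and Wnt lists, 0.656 for p53 targets, 0.716 for proliferation and 0.756 for stem cell genes. The fetal (adjusted p = 0.0611) and Wnt lists (0.0586) no longer passed with quantile normalization. Of the members of these 7 lists Bmpr1a alone passed over all genes. Adjusted over the list alone, 3 fetal, 2 kinase inhibitor, 2 TGF-beta, 2 p53, 1 Wnt, 0 proliferation and 0 stem cell genes passed.

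The diseased arrays were not in the fit that called the Ezh2 genes, although they took part in the filter and the choice of probes, and their wild-type comparators were in the fit. Of the 23 genes that rose with Ezh2 loss, 23 (LSK MDS/MPN), 22 (LSK RAEB), 21 (GMP MDS/MPN) and 21 (GMP RAEB) lay above both Ezh2 wild-type arrays of the cell type, against 39.4, 43.1, 62.4 and 46.2% of all genes. The 3 genes that fell lay below both on each diseased array. Ly6k was the largest exception and differed by -1.96 (MDS/MPN) and -2.29 (RAEB) from the Ezh2 wild-type GMP arrays. The count of 26 was 7 with the arrays' sex pattern as a covariate, 15 with quantile normalization and 75 with normexp. Leaving out 1 array gave 4 (without LSK wild-type), 9 (LSK Tet2 knockdown), 10 (LSK Ezh2-null), 7 (LSK double), 4 (GMP Tet2 knockdown) and 0 genes (without GMP wild-type, GMP Ezh2-null or GMP double).

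The Ezh2 effects in GMPs and in LSK cells were compared to ask whether they differ. The largest positive values were Fkbp10 (3.64, SE 0.52), the eosinophil ribonuclease gene Rnase2a (3.61, SE 1.15), Nupr1 (3.41), Plxdc2 (3.31) and Rhoj (3.29). The largest negative values were the lymphoid recombinase gene Rag2 (-2.40, SE 0.61), Dusp19 (-2.40), Atf3 (-2.31), Kctd15 (-2.27) and the cytokine receptor gene Flt3 (-2.23, SE 0.25). None passed in limma (0 of 13706 genes, smallest adjusted p = 0.0577), with 802 genes at an unadjusted p under 0.05 and 685.3 by chance. With trend and robust options limma gave 4 genes, and with normexp 6. Tet2 (-0.46) and Ezh2 (-0.18) had an adjusted p of 1.00.

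As lists, 17 of 30 differed between the cell types in their Ezh2 effect, and 0 did with an estimated correlation (adjusted p from 0.305 to 0.641 for these 17). The effect was lower in GMPs for immediate-early (0 of 24 positive, median -0.97), inflammatory response (4 of 23, -0.54), lymphoid-primed progenitor (2 of 18, -0.52), B-lymphoid (4 of 12, -0.42), monocyte and macrophage (6 of 20, -0.27), p53 target (7 of 22, -0.23) and proliferation genes (12 of 37, -0.13). It was higher in GMPs for mast cell, basophil and eosinophil (17 of 21, 0.94), HoxB (5 of 5, 0.72), megakaryocyte and platelet (20 of 23, 0.70), neutrophil (16 of 22, 0.54), HoxA (6 of 9, 0.50), haematopoietic stem cell (29 of 35, 0.47), stromal and endothelial (9 of 13, 0.33), developmental transcription factor (19 of 23, 0.29), Wnt signalling (16 of 22, 0.26) and fetal and imprinted growth genes (9 of 13, 0.25). The immediate-early list lay lower on the wild-type LSK array than on the other 3 LSK arrays without disease (by 0.91 to 1.20), which by itself raises the LSK effect. No member passed over all genes. Adjusted over the list alone, 6 lymphoid-primed, 4 B-lymphoid and 1 monocyte gene were lower, and 7 stem cell, 5 megakaryocyte, 2 HoxA, 2 HoxB, 2 developmental and 1 B-lymphoid gene were higher. With quantile normalization the neutrophil list no longer passed (adjusted p = 0.0508).

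Tet2 knockdown gave no gene past the threshold in limma (0 of 13706, smallest adjusted p = 0.175), with 786 genes at an unadjusted p under 0.05 and 685.3 by chance; trend and robust options also gave 0. The largest positive values were Upb1 (2.47, SE 0.37), an enzyme gene of pyrimidine breakdown, the kinase gene Alpk1 (1.90, SE 0.36), Bcar3 (1.41), the MHC class II gene H2-Eb1 (1.22) and Entpd2 (1.21). Among the largest negative values were Rbm44 (-2.22, SE 0.54), Tet2 itself (-1.92) and the eosinophil granule genes Epx (-1.35) and Prg2 (-1.27). The Prg2 spot was low on the LSK double mutant array (-1.31, median of the other LSK arrays 1.31), and its matched pairs ran from -2.62 to -0.01. Ezh2 differed by -0.12 (adjusted p = 0.838).

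As lists, mast cell, basophil and eosinophil genes fell with Tet2 knockdown (4 of 21 positive, median -0.57) and interferon response genes rose (30 of 37 positive, median 0.22, Gbp2 at 0.68 and Isg15 at 0.49). Immediate-early genes rose (24 of 24 positive, median 0.38, Ier2 at 0.59), inflammatory response genes rose (19 of 23 positive, median 0.32, Cd14 at 0.74), and dendritic cell genes rose (11 of 13 positive, median 0.10, H2-Aa at 1.27 and Cd74 at 1.17). HoxA genes fell (4 of 9 positive, median -0.36, Hoxa7 at -0.62 and Hoxa9 at -0.52), and neutrophil genes fell (5 of 22 positive, median -0.39, Camp at -1.38). No member passed over all genes, and adjusted over the list alone only 4 HoxA genes did. With an estimated correlation the adjusted p was 0.670 for the mast cell, interferon, HoxA, neutrophil and dendritic lists, 0.848 for inflammatory and 0.940 for immediate-early genes. In LSK cells the immediate-early list was 1.20 above wild-type with Tet2 knockdown, 0.98 in Ezh2-null and 0.91 in double mutant cells, so the wild-type LSK array stands apart in this list too.

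The Tet2 by Ezh2 interaction asks whether the double mutant differs from the sum of its parts. It called 5 genes in limma: Xist (15.2, SE 1.04) and Zfp963 (3.67, SE 0.26) were positive, and the Y-linked genes Eif2s3y (-16.8, SE 0.47), Ddx3y (-13.8, SE 0.34) and Uty (-7.51, SE 0.25) were negative, with adjusted p from 0.000567 to 0.0380. These sizes are not exact, since the dimmer side lay at background on each array, or on 3 of 4 arrays for Zfp963 (0.87 to 3.87 over the alternatives). Values that did not pass were Syce1 (8.85), Mrgpra2a (4.77), the chemokine receptor gene Ccr2 (4.64) and the heat shock genes Hspa1a (-6.04) and Hspb1 (-4.06). Tet2 (0.42, adjusted p = 0.956) and Ezh2 (-0.16, adjusted p = 0.958) did not pass. Limma gave 707 genes at an unadjusted p under 0.05 against 685.3 by chance. Xist passed in 8 of 16 alternatives and Zfp963 in 5 of 17, counts that include the identical authors' value table. The term coincides with the sex pattern of the arrays, so the 2 cannot be told apart by this test. As lists, granulocyte-macrophage progenitor (21 of 24 positive, median 0.24), neutrophil (15 of 22, 0.49) and monocyte and macrophage genes (14 of 20, 0.28) were positive, and immediate-early (1 of 24, -1.18), inflammatory response (4 of 23, -0.65) and p53 target genes (4 of 22, -0.36) were negative. Their adjusted p with an estimated correlation was 0.437, 0.940, 0.940, 0.940, 0.984 and 0.940. Of their members 0 passed over all genes, and 6 immediate-early genes and 1 inflammatory gene passed adjusted over the list alone. Medians in LSK cells and GMPs were 1.23 and 0.35 for neutrophil, 0.51 and 0.05 for monocyte and macrophage, and 0.28 and 0.38 for granulocyte-macrophage progenitor genes. For neutrophil genes the wild-type LSK array lay above the other LSK arrays without disease, which by itself raises the LSK value. Against wild-type, the immediate-early list was at 1.20, 0.98 and 0.91 in LSK cells and at 0.98, 0.12 and -0.36 in GMPs (Tet2 knockdown, Ezh2-null and double mutant), so in LSK cells its negative value comes with the wild-type array standing apart from the other 3.

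The double mutant was compared with wild-type directly. Among the higher genes were Dnm3 (at least 32.2-fold, its spot lies at the edge of the array), Bmpr1a (at least 29.6-fold), Fndc4 (3.92), Dsp (3.84, SE 0.50) and Zfyve9 (at least 12.0-fold). Among the lower genes were the neutrophil granule genes Camp (-3.10, SE 0.97) and Ltf (-2.38, SE 0.89), Nqo1 (at least 7.64-fold, spot in a dark corner of the LSK double mutant array), Rbm44 (at least 6.07-fold) and Creb3l3 (-2.44). Tet2 was -1.91 (SE 0.73) and Ezh2 -0.11 (SE 0.38). No gene passed in limma (0 of 13706, smallest adjusted p = 0.163), with 433 genes at an unadjusted p under 0.05 and 685.3 by chance; trend and robust options also gave 0, and leaving out the GMP double mutant array gave 5. As lists, interferon response (32 of 37 positive, median 0.54), cyclin-dependent kinase inhibitor (6 of 7, 0.45), lymphoid-primed progenitor (13 of 18, 0.36), Wnt signalling (13 of 22, 0.08) and fetal and imprinted growth genes (9 of 13, 0.03) were higher, and neutrophil (4 of 22, -0.69), mast cell, basophil and eosinophil (4 of 21, -0.37) and HoxB genes (0 of 5, -0.25) were lower. The adjusted p with an estimated correlation was 0.155 for interferon, 0.823 for Wnt, 0.661 for fetal and 0.678 for the other 5 lists. With quantile normalization the fetal list no longer passed (adjusted p = 0.0816). Adjusted over the list alone, 2 interferon genes, 1 kinase inhibitor gene, 1 fetal gene and 1 HoxB gene passed. Medians in LSK cells and GMPs were -1.26 and -0.06 for neutrophil, -0.60 and -0.08 for mast cell and -0.83 and -0.01 for HoxB genes. Lymphoid-primed genes were at 0.73 and 0.11, so these 4 directions come mainly from LSK cells. Interferon (0.54 and 0.56) and kinase inhibitor genes (0.26 and 0.60) were higher in both. The wild-type LSK array stands apart in neutrophil genes, as described above.

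The diseased double mutants were compared with double mutants without disease. Granulocytic genes stood out: as lists, neutrophil genes rose (21 of 22 positive, median 2.22, Camp at 3.06 and Cd177 at least 5.51-fold) and mast cell, basophil and eosinophil genes rose (17 of 21 positive, median 0.86, the eosinophil granule genes Prg2 at 4.05, Epx at 3.34 and Prg3 at 2.16). The LSK double mutant comparator was itself below wild-type LSK cells in neutrophil genes (list median -1.26). Its Prg2 spot was low as well (-1.31, median of the other LSK arrays 1.31), which enlarges the Prg2 value. Monocyte and macrophage genes rose (16 of 20 positive, median 0.80, Lgals3 at 1.59), as did megakaryocyte and platelet genes (22 of 23 positive, median 0.63, the platelet integrin gene Itga2b at 1.85), granulocyte-macrophage progenitor genes (20 of 24 positive, median 0.59, Cebpa at 0.91) and p53 target genes (18 of 22 positive, median 0.42, Pmaip1 at 1.19). Interferon response genes fell (11 of 37 positive, median -0.23, Ifi44 at -1.87). Under an estimated correlation the adjusted p was 0.891 for the neutrophil, mast cell, monocyte and interferon lists and 0.980 for the other 3. The granulocyte-macrophage progenitor and p53 target lists no longer passed with quantile normalization (adjusted p = 0.0569 for both). No listed member passed over all genes; adjusted over the list alone, 7 mast cell, basophil and eosinophil genes, 3 monocyte genes, 2 interferon genes, 1 neutrophil gene and 1 megakaryocyte gene did.

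Of single genes, Bst1, a surface enzyme of myeloid cells, was at least 5.16-fold higher in disease (2.40, SE 0.21, adjusted p = 0.0496, higher in 4 of 4 pairs). It was named after its value was seen, since it lay well above background on 3 of the 4 diseased arrays. Among the other higher genes were Wwtr1 (at least 22.9-fold, edge spot), Trnp1 (4.05), the eosinophil gene Ear1 (3.70) and Rabif (3.66, same dark corner of the LSK double mutant array), and among the lower ones Syce1 (at least 48.1-fold), Dnm3 (at least 33.9-fold) and Trim29 (at least 22.5-fold), the last 2 edge spots, Xist (-3.89) and Ly6k (-3.50). Tet2 (-0.94, SE 0.63) and Ezh2 (0.06, SE 0.33) did not pass. Limma gave 1879 genes at an unadjusted p under 0.05 against 685.3 by chance, yet Bst1 alone passed, and with trend and robust options 0 genes did; without the LSK RAEB array the count was 21, without the GMP double mutant array 6, and 0 without any other array. Disease and slide cannot be told apart, because no slide held both diseased and other arrays. In GMPs the sex-linked pattern differs as well: both diseased arrays had Y-linked signals, and the double mutant array had Xist. Xist there was at -6.73 and -6.76 against the double mutant array, so its fall cannot be told apart from donor sex. In LSK cells, where these arrays all had Xist, it read 1.35 and 1.63 against 2.52.

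RAEB was compared with MDS/MPN in the fit of cell type and condition, which has no slide term; the 2 arrays of each cell type shared a slide. The eosinophil genes were lower in RAEB, with values of -4.00 (SE 0.59) for Prg3, -3.82 for Ear1, -3.78 for Rnase2a, -3.75 for Ear10 and -3.65 for Ear6. The last 4 are closely related ribonuclease genes with similar sequences. Among the higher genes were Btnl10 (at least 12.0-fold), Ephb1 (at least 9.62-fold) and Olfr95 (at least 8.34-fold), all edge spots, the activation marker gene Cd83 (3.37, SE 2.14) and the immediate-early gene Nr4a1 (2.92, SE 1.93). No gene passed in limma (0 of 13706, smallest adjusted p = 0.355), with 364 genes at an unadjusted p under 0.05 against 685.3 by chance; trend and robust options also gave 0. With slide as a block 2 genes passed. Without the LSK RAEB array the count was 358, and without the GMP RAEB array it was 1. Tet2 (-0.63) and Ezh2 (0.06) had adjusted p of 0.976 and 0.997.

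As lists, mast cell, basophil and eosinophil genes fell in RAEB (2 of 21 positive, median -1.70, 6 adjusted over the list alone), erythroid genes fell (6 of 23 positive, median -0.72, Klf1 at -0.99, 3 adjusted over the list alone), and neutrophil genes fell (3 of 22 positive, median -0.86, Camp at -3.63). Proliferation genes (5 of 37 positive, Plk1 at -0.57) and granulocyte-macrophage progenitor genes (1 of 24 positive, Elane at -1.10) fell as lists. Immediate-early genes rose (24 of 24 positive, median 1.20, Junb at 1.24), as did inflammatory (20 of 23, Ccl4 at 2.32), interferon response (30 of 37, Irf7 at 1.73), p53 target (18 of 22, Phlda3 at 1.98) and B-lymphoid genes (10 of 12, median 0.92, Cd79a at least 3.87-fold). The adjusted p with an estimated correlation was 0.138 for the mast cell, erythroid and interferon lists, 0.613, 0.669 and 0.609 for neutrophil, proliferation and progenitor genes, 0.460 for immediate-early and inflammatory genes, and 0.298 for p53 and B-lymphoid genes. Of the members of these 10 lists, 0 passed over all genes. The 2 cell types did not go the same way in several of these lists, with medians in LSK cells and GMPs of -3.65 and 0.70 for neutrophil, 0.14 and -0.66 for proliferation, -0.01 and 0.95 for p53 target and 2.30 and -0.23 for B-lymphoid genes, so for these the direction given comes from 1 cell type. Of the remaining lists, HoxA, HoxB, dendritic cell, T and NK cell and lymphoid-primed genes were higher in RAEB, with adjusted p of 0.609, 0.501, 0.266, 0.609 and 0.609 with an estimated correlation; in GMPs the medians were -0.03 for T and NK cell and -0.06 for lymphoid-primed genes, against 0.62 and 0.31 in LSK cells. With quantile normalization the HoxA (adjusted p = 0.158), T and NK cell (0.128), lymphoid-primed (0.0803) and granulocyte-macrophage progenitor lists (0.0622) no longer passed.

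Single arrays show where the disease lists came from, as sizes without a test. Percentiles place a list's median among 10000 random lists; each list named here lay at percentile 100 when higher and 0 when lower, unless another value is given. On the LSK MDS/MPN array, neutrophil genes were 3.77 above the LSK double mutant array, mast cell, basophil and eosinophil genes 2.31, monocyte genes 1.23 and granulocyte-macrophage progenitor genes 1.18, while immediate-early genes were at -2.39. Among its largest values were the granulocyte genes Lrg1 (at least 76.5-fold), Chil3 (5.71), Camp (5.49) and Prg2 (5.87), and Nr4a1 (-5.60) and Cd83 (-5.57). The Prg2 spot was low on the comparator, the LSK double mutant array (-1.31, median of the other LSK arrays 1.31). On the LSK RAEB array, monocyte genes were 1.36 and B-lymphoid genes 1.15 above the LSK double mutant array, with the pre-B cell receptor gene Vpreb3 at 5.08, the antibody chain gene Jchain at least 98.7-fold lower and the neutrophil list at 0.53 (percentile 99.94). For the neutrophil list the LSK double mutant array was itself below wild-type LSK cells (median -1.26), so 0.53 is no rise over wild-type.

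On the diseased GMP arrays, neutrophil genes were 1.94 (MDS/MPN) and 2.34 (RAEB) above the GMP double mutant array, megakaryocyte and platelet genes 1.08 and 1.44, and immediate-early genes 1.18 and 1.75. The GMP MDS/MPN array had Ear1 at 6.35 and the platelet chemokine gene Ppbp at least 68.7-fold higher, with erythroid genes 0.74 higher. The GMP RAEB array had Chil3 at 8.19, Chil4 at least 222-fold and Stfa1 at least 68.8-fold higher, all genes of the granulocyte or macrophage lineages; p53 target genes were 1.08 and inflammatory genes 1.29 higher, and proliferation genes were at -0.48 (percentile 0.06). These are the disease lists of 1 array each, on other slides than their comparators, and in GMPs with the opposite sex-linked pattern.

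**Figure D3:**
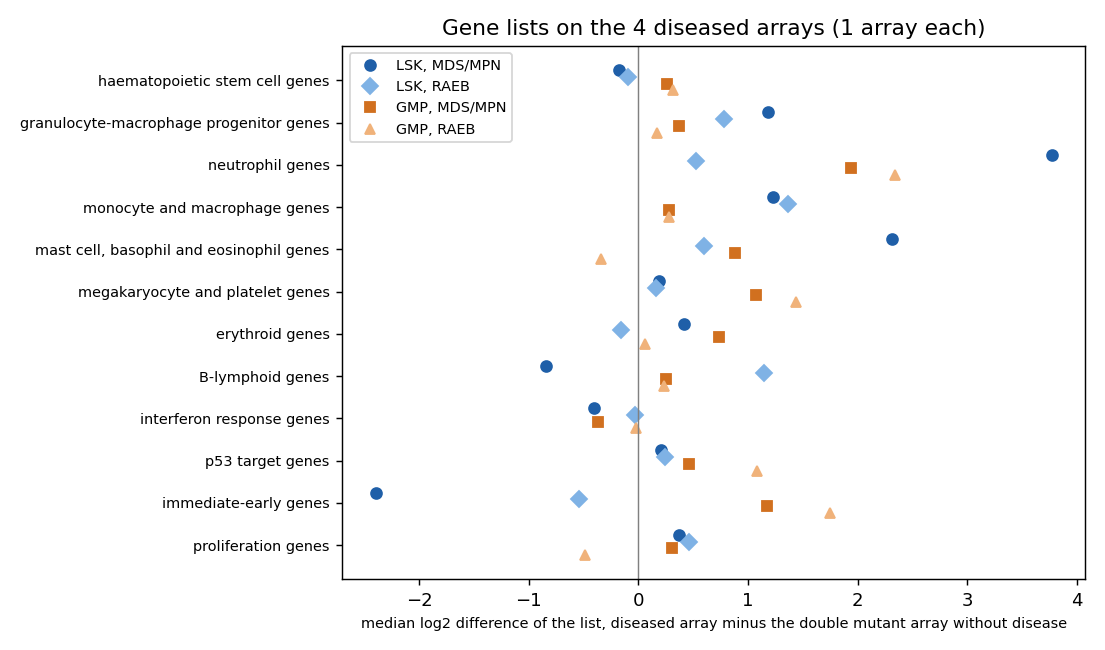
Median log2 difference of 12 gene lists (y axis) between each diseased array and the double mutant array of its cell type without disease (x axis), with 1 point per diseased array. The neutrophil list lies at 3.77 for LSK MDS/MPN, 0.53 for LSK RAEB, 1.94 for GMP MDS/MPN and 2.34 for GMP RAEB. For this list the LSK double mutant array itself had a median of -1.26 against wild-type LSK cells.

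Against wild-type of the same cell type, the number of genes at least 2-fold apart was larger on the diseased arrays than on the others. The diseased arrays lay on other slides than wild-type, and the others on the same slide. Disease and slide therefore cannot be told apart in these counts. In LSK cells it was 853 with Tet2 knockdown, 806 in Ezh2-null, 627 in double mutant, 1640 in MDS/MPN and 1776 in RAEB cells. In GMPs it was 485, 630, 744, 1802 and 2520 in the same order. Among the largest values in GMPs were the retinol-binding protein gene Rbp4, at least 79.6-fold higher in Ezh2-null and at least 40.7-fold in double mutant cells, and Igf2bp3, at least 38.0-fold and at least 57.7-fold higher. With normexp the counts were smaller, from 113 (GMP Tet2 knockdown) to 1238 (GMP RAEB).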

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

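The tests weighed in this part were chosen after the results had been seen. The test of the Tet2 by Ezh2 interaction picked out 5 genes whose Ezh2 effect differed between the Tet2 genotypes: Xist (15.21), Zfp963 (3.671), Eif2s3y (-16.76), Ddx3y (-13.8) and Uty (-7.51), as log2 differences of differences over 8 arrays. The sizes are not exact, since the dimmer side lay at background on each array, or on 3 of 4 arrays for Zfp963. A candidate explanation for 4 of them is the sex of the donor cells. Xist and the Y-linked Eif2s3y, Ddx3y and Uty are the 4 genes of the sex-linked list that were tested, and all 4 were among the 5 called. On 11 of the 12 arrays either Xist or all 3 Y-linked genes were well above background and not the other, as 1 donor sex per array needs. The GMP MDS/MPN array lacked Xist and had Eif2s3y and Ddx3y, with Uty (-3.66) at background, so the pattern is incomplete there and the explanation stays a candidate. Uty still lay above its values on the Xist-positive arrays (-6.647 to -6.085). Wild-type and double mutant arrays had Xist and lacked the Y-linked signals, and the arrays of either single mutant had the reverse, so on these 8 arrays the sex of the donors follows the interaction term exactly in both cell types. A response of these genes to the combined genotype is argued against in GMPs by the 2 diseased double mutant GMP arrays, where 8 of 8 values of the 4 genes lay nearer to the single mutant than to the double mutant GMP array (Xist at -5.56 and -5.59). On the 2 diseased double mutant LSK arrays 0 of 8 values did (Xist at 1.35 and 1.63). In LSK cells this comparison therefore cannot tell such a response from donor sex. The wild-type LSK array, with neither mutation, read like the double mutant one (Xist 2.57 and 2.52, Eif2s3y -6.25 and -6.38). The pattern there is thus not particular to the combined genotype.

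Zfp963 has another pattern. Its mean was -5.54 on the Y-positive GMP arrays and -3.51 on the Xist-positive GMP arrays without disease. On the diseased GMP arrays, which carry Y-linked signals and no Xist, it read -3.37 (MDS/MPN) and -2.28 (RAEB), so 0 of these arrays lay nearer to the Y-positive ones, which argues against donor sex as the whole explanation for Zfp963. A difference between donors other than sex, the disease, the slide and the combined genotype stay open for it, untested.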

How the results depend on the processing

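Some alternatives were added after the data had been seen: the sex covariate, probes without a symbol, slide as a random block, the 8 arrays without disease and leaving out edge probes. Of the genes chosen for naming, 95 values past the threshold kept their sign under each alternative run; of 226 values not past it, 24 changed sign in at least 1 alternative (41 of 4667 alternative values, 0 of them past the threshold), such as Elane in RAEB against MDS/MPN (-1.10, highest 0.12). With quantile normalization the majority changed sides between genes higher and lower for GMP against LSK (3525 and 2583 became 2641 and 3105), LSK MDS/MPN against wild-type (781 and 859 became 988 and 703), LSK RAEB against wild-type (799 and 977 became 1014 and 750) and GMP RAEB against wild-type (1263 and 1257 became 1199 and 1224). Normexp turned the last 3 as well, to 296 and 261, 332 and 321, and 518 and 720. The interaction, 2 higher and 3 lower, became 3 and 2 with the filter of at least 6 of 12 arrays and 5 and 4 with symbol-less probes; the causes were not tested. GMP against LSK stayed within 1.5 times of 6108 genes throughout (4480 to 6767 when 1 array was left out). The Ezh2 loss count of 26 became 15 with quantile normalization, 75 with normexp, 12 with no filter, 77 with trend and robust options, 9 in the fit of 12 arrays, 7 with the sex covariate, 12 with symbol-less probes kept and 44 without edge probes; 15, 14, 12, 21, 8, 6, 12 and 25 of these were among the 26. Leaving out 1 array gave 0 to 10 genes: 4 without LSK wild-type, 9 without LSK Tet2 knockdown, 10 without LSK Ezh2-null, 7 without LSK double, 4 without GMP Tet2 knockdown, and 0 without GMP wild-type, GMP Ezh2-null or GMP double.

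The Tet2 knockdown count of 0 stayed 0 under the other settings and ranged from 0 to 1 when 1 array was left out (1 without LSK or GMP wild-type). The interaction count of 5 became 3 with quantile normalization, 14 with normexp, 3 with no filter, 10 with trend and robust options and 9 with symbol-less probes, and 3 to 7 when 1 array was left out (3 without LSK double or GMP Tet2 knockdown, 7 without GMP double). The difference of Ezh2 effects between cell types went from 0 to 6 with normexp, 4 with trend and robust options and 2 without edge probes, and 0 to 1 when 1 array was left out (1 without LSK Ezh2-null or GMP Tet2 knockdown). The double mutant against wild-type gave 0 to 5 (5 without GMP double). The diseased count of 1 became 0 with normexp, no filter, the filter of at least 6 of 12 arrays, trend and robust options, slide as a random block or only the arrays compared, and 2 with symbol-less probes; leaving out 1 array gave 0 to 21 (21 without LSK RAEB, 6 without GMP double). RAEB against MDS/MPN went from 0 to 2 with slide as a block and 0 to 358 when 1 array was left out (358 without LSK RAEB, 1 without GMP RAEB). Keeping more probes or no filter enlarges the number of genes adjusted for, and leaving out edge probes reduces it; for the other settings the cause was not tested.

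With an estimated correlation the lists called went from 18 (GMP against LSK), 12 (Ezh2 loss), 7 (Tet2 knockdown), 6 (interaction), 17 (difference of Ezh2 effects), 8 (double mutant), 7 (disease) and 15 (RAEB) to 0 in each. With normexp the genes at least 2-fold from wild-type numbered 155 (Tet2 knockdown), 206 (Ezh2-null), 140 (double), 557 (MDS/MPN) and 653 (RAEB) in LSK cells and 113, 166, 150, 684 and 1238 in GMPs; the cause was not tested. Among the values of named genes, 310 of 321 were rated the same with quantile normalization, 302 with normexp and 315 with trend and robust options. The rating means the same side of the threshold and, for values past it, the same sign. A value not past it could change sign and still be rated the same if it shifted by no more than its SE. Signal over background limits the dim genes. Where a group lay at background, the size is a lower bound under the main scaling only. Alternatives gave smaller log2 sizes, such as -2.85 for Gimap8 and -4.06 for Mycn in GMP against LSK, and 1.12 for Bmpr1a with Ezh2 loss.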

Other observations

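The tests of the Ezh2 genes on the diseased arrays, of the neutrophil genes and of the dark corner were chosen after the results had been seen; the counts of other splits were planned. On single LSK arrays without disease, lymphoid lists lay above the wild-type array where Ezh2 was lost. Lymphoid-primed progenitor genes were 0.72 higher in Ezh2-null and 0.73 in double mutant cells (percentile 100 of random lists for both), B-lymphoid genes 0.61 and 0.68, and T and NK cell genes 0.51 and 0.38. Megakaryocyte and platelet genes were at -0.50 and -0.64, and haematopoietic stem cell genes at -0.22 and -0.24. All 5 medians of each array rest on 1 wild-type array, and none was tested.

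In GMPs the double mutant array had interferon response genes 0.56 above wild-type (percentile 100), HoxA genes 0.65 (percentile 99.74) and cyclin-dependent kinase inhibitor genes 0.60 (percentile 99.99), the last 1.15 and 1.24 on the MDS/MPN and RAEB arrays. The opioid peptide precursor gene Penk was at least 45.0-fold higher in double mutant GMPs than in wild-type. Hif3a, higher by 1.07 with Ezh2 loss in GMPs, was 4.50 above the Ezh2 wild-type arrays on the GMP RAEB array. The heat shock genes Hspa1a (4.97) and Hspb1 (at least 25.5-fold) were higher on the GMP Tet2 knockdown array than in wild-type.

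The hypothesis that genes that follow Ezh2 loss in one cell type also do so in diseased arrays of the other cell type was tested with the 50 genes highest with Ezh2 loss in each cell type. Of those chosen in LSK cells, 42 (MDS/MPN) and 41 (RAEB) lay above both Ezh2 wild-type GMP arrays, or 84% and 82% against 62.4 and 46.2% of all genes. Of those chosen in GMPs, 45 and 40 lay above both Ezh2 wild-type LSK arrays, or 90% and 80% against 39.4 and 43.1%. The lowest count was thus 40 of 50, and the genes were ranked on arrays of the other cell type, although the diseased arrays took part in the filter and in the choice of 1 probe per gene. An Ezh2 effect that persists in disease is consistent with these counts, although the diseased arrays were hybridised on other slides.

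Neutrophil genes were 3.77 above the double mutant array on the LSK MDS/MPN array, with 21 of 22 listed genes higher. S100a9 read 7.60 there, 2.72 on the double mutant and 5.80 on the wild-type LSK array, and Camp 4.88, -0.61 and 3.13. Of the 22 genes, 16 were well above background on the wild-type and 15 on the double mutant LSK array, so lower levels of them are found in LSK sorts without disease, and 0 stand on another list. A slide effect is argued against by the LSK RAEB array of the same slide, where 20 of 22 genes were lower, with a median difference of -3.645 (interquartile range -4.50 to -0.98). RNA of GMPs in the sort is argued against as well: the GMP genes would need 13.7% RNA like that of the double mutant GMP array, 10.1% like MDS/MPN or 12.6% like RAEB, and the neutrophil genes lay above each mixture, by a median of at least 0.9852. RNA of neutrophils in the sort could give the pattern and cannot be told apart from expression by the LSK cells, since no neutrophil array sets the share needed; the LSK gate removes lineage-positive cells. Expression of these genes by diseased LSK cells stays open, untested, and 1 array carries the pattern.

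The LSK double mutant array had 10 spots more than 2 (log2) below every other LSK array, and 8 of them lay in 1 corner. Their median distance was 10 spots, against 138.5 for random sets (lowest 56.36; permutation p = 1e-04, the smallest that 10000 sets can give), so a damaged patch of the array is a likely source. For Ago4 and Irf2bpl, which have another probe elsewhere, that probe differed from the other LSK arrays by -0.08 and 0.50 (median 0.2083), which argues against an effect of the double mutant. For the other 6 corner genes, among them Rabif, Nqo1 and Ccdc117, no other probe named for the gene passed the filter, and probes without a symbol were not searched. On the 2 diseased LSK arrays, which are double mutant too, 12 of 12 values of these 6 genes lay nearer to the other 3 genotypes, and they were above the LSK double mutant array by a median of 4.06, which argues against the double mutant itself. A change found in double mutant LSK cells without disease alone stays open, untested. Cxcr1 and Prg2, the low spots outside the corner, had no such test.

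Other splits of the arrays were fitted in the same way. For GMP against LSK, 1 of 100 splits of the 12 arrays, the real one, gave as many genes (6108, highest other 15). Splits that mix the cell types leave the large cell type difference in their spread. Their low counts were largely fixed in advance, so this count alone does not exclude chance. For Ezh2 loss, 33 splits of the 8 arrays could be fitted beside the other terms, and 1 of these 33, the real one, gave as many genes (26). The highest other count was 4, from the split that follows the sex pattern. The other splits leave the Ezh2 difference in their spread, which lowers their counts. The count of 26 fell to 0 without GMP wild-type, GMP Ezh2-null or GMP double, so chance is not excluded. For Tet2 knockdown the real split gave 0 genes, so each of the 33 splits had to give as many, and the count says nothing about chance; the highest other, 8, came from the split by sex pattern.

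Syce1 was high on some arrays and at background on others, being at least 132-fold lower on the LSK Tet2 knockdown array and at least 190-fold lower on the LSK MDS/MPN array than in wild-type LSK cells.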
